A study of Mus musculus with 24 samples.

How the data were processed

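RNA was sequenced from cells sorted from the lungs of female Balb/c mice that were 8 weeks old. The mice were sham-irradiated and given a control IgG antibody, irradiated on the lungs with 13 Gy and given the control IgG, or irradiated and given daily injections of an antibody against Ly6G, a surface protein of neutrophils. Lungs were taken 7 days after irradiation. Cells without the leukocyte marker CD45, the endothelial marker CD31 and the erythroid marker Ter119 were sorted into EpCAM-positive (epithelial) and EpCAM-negative (mesenchymal) fractions. The protocol text of the labels names CD45 in the place of CD31 in the gate, while the cell type entries name CD31. Total RNA was depleted of ribosomal RNA and made into 1 library per sample, which gave 4 libraries, each from 1 mouse, in each of the 6 groups and 24 libraries in all.

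The authors listed cutadapt 1.5, STAR 2.2.2a (the version as listed), SAMtools 1.8, RSEM 1.3.0 and DESeq2 without a version, with the mouse genome build GRCm38. The deposited tables, 1 per compartment, hold a signal in normalised counts, gene counts divided by 1 size factor per library, for 48795 gene identifiers. Every positive value of a column was a whole multiple of 1 step within 0.001, so whole reads could be recovered from 100% of the values. For mesenchymal sham replicate 3 and irradiated depleted replicate 4 the step lay within 1% of 1, which tells little about the scale. Each table has its own scale, so no level was compared between the tables. A symbol was found for 48349 identifiers in GENCODE release M21 on GRCm38, from which gene positions were also taken. The annotation release used by the authors is not stated, and the reference genome is that of another strain than Balb/c.

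Recovered reads per library ranged from 8159062 to 13373329 in the epithelial table and from 7366672 to 11408083 in the mesenchymal table. A count of 0 in a library allows up to 3 reads, which is a normalised count of 2.36 to 3.81 in the epithelial table and of 2.48 to 3.66 in the mesenchymal table. These limits cover counting error alone, since reads without molecular identifiers are not independent molecules. Within each group the 36 pairs of libraries were checked for copies of the same material. Their counts differed by more than counting error in every pair (chi-square per degree of freedom 2.45 to 17.0, Pearson r across genes 0.971 to 0.990).

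The samples, tests, gene lists and rule for named genes were fixed before the data were examined. Values were tested as log2(value + 1) with limma 3.58.1 (limma-trend, robust) in R 4.3.3, with 1 mean per group and the 3 groups of a compartment in 1 fit. Genes needed a normalised count of at least 10 in at least 4 of the 12 libraries of the table, which left 16626 genes in the epithelial and 16624 in the mesenchymal table. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Errors given with log2 changes are the standard errors of that fit, and errors given with means are standard deviations over 4 libraries. The comparisons were irradiated against sham, depleted (irradiated with the Ly6G antibody) against irradiated, and depleted against sham. The difference between the responses of the compartments was tested on the 15092 genes tested in both tables, in a fit of all 24 libraries. An irradiation score was computed per library over genes that differed between both irradiated groups together and sham. The score is the mean distance on the log2 scale from the sham mean, signed by the direction of each gene. Depleted and irradiated scores were compared by an exact two-sided permutation test over 70 assignments, whose smallest p is 0.0286.

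Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a comparison that had at least 5 tested members. The pathway lists were p53 targets, cell cycle, senescence and secreted factors, type I interferon response, antigen presentation, Notch pathway, Wnt pathway, YAP and TAZ targets, extracellular matrix and TGF-beta targets, inflammatory cytokines and NF-kB targets, cholesterol synthesis, fatty acid synthesis, oxidative stress response, and unfolded protein response. The cell type lists were alveolar type 2, alveolar type 1, transitional alveolar epithelium, club and secretory, ciliated, basal, alveolar fibroblast, adventitial fibroblast, smooth muscle and myofibroblast, pericyte, mesothelial, endothelial, leukocyte, neutrophil, macrophage, lymphocyte, erythroid and platelet, glial, pan-epithelial, dissociation stress and immediate early, and mitochondrially encoded. Some genes stand in more than 1 list. Named genes were, per compartment and for irradiated against sham and depleted against irradiated, the 10 largest rises and 10 largest falls among called genes whose 4 libraries in each group did not overlap and whose mean was at least 50 in the higher group. Predicted and small RNA genes were left out. Up to 4 members of each list with the smallest unadjusted p and 17 genes fixed in advance were added. For depleted against sham the same genes were described.

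Alternatives were other pseudocounts (0.5, 8), filters, rescalings (TMM, equal totals), library weights, replicate number as a block, no robust option, fits of the compared groups alone, each library left out in turn, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and for the score a median and genes chosen from a part of the libraries. Chosen after the data were seen were reads thinned to the smallest library of a table, the leukocyte marker level as a covariate, and removal of each library's trend on gene length and GC content. The same replicate number in different groups was not said to mark a shared animal or day. Residuals of libraries with the same number in different treatments had a median correlation across genes of 0.04 in each table. Yet replicate 2 had the highest mean leukocyte marker level in every group. In sham, irradiated and depleted libraries this level was 5.38, 6.60 and 6.02 (epithelial) and 5.79, 6.84 and 6.51 (mesenchymal). The low median therefore does not exclude a factor shared by replicate number. Across the compartments the residuals of the same treatment and number correlated at a median of 0.107, and 8 of 12 libraries had their best match in the library of that number. The median was -0.02 for other numbers of the same treatment. Whether these libraries come from the same mouse is not stated, so no block was used in the main test.

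The calls were tested on simulated data made from the deposited libraries with known changes. Of genes changed 2-fold, 64% to 79% were recovered in the comparisons within a table and 62% in the difference between compartments, and of genes changed 4-fold 92% to 97%. False calls were 2.82% to 8.94% of the calls. The score recovered 101% and 100% of a response of 100%, and 51.8% and 53.2% of a response of 50%. With p53 targets changed, 0 of 33 other lists were called by camera in either table. The simulated genes were drawn independently, so this leaves the effect of correlation between genes on camera untested. Values and figures were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.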

Results

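RNA was measured in 24 libraries of sorted epithelial and mesenchymal lung cells, 4 in each of 6 groups. The groups were sham-irradiated, irradiated (13 Gy) and irradiated with neutrophil depletion by an antibody against Ly6G, 7 days after irradiation. Reads per epithelial library were 9776113 to 11710964 in sham, 10884703 to 13373329 in irradiated and 8159062 to 9267632 in depleted mice. Mesenchymal libraries held 8951233 to 11408083 reads in sham, 7366672 to 8989716 in irradiated and 8960347 to 9932700 in depleted mice. Between 22848 and 24672 genes had a count above 0 in an epithelial library, and between 22820 and 24324 in a mesenchymal library. Mean shares of reads from mitochondrial genes were 1.97%, 1.93% and 1.73% in epithelial sham, irradiated and depleted libraries, and 0.818%, 0.692% and 0.695% in mesenchymal ones.

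The first question was what irradiation changed in the epithelium. Phlda3 (ENSMUSG00000041801, GRCm38 chromosome 1, start 135766119, end 135769136), a p53 target that restrains Akt signalling, rose from a normalised count of 32.3 ± 3.06 (SD, n = 4) in sham to 413 ± 86.9 in irradiated mice. The log2 change was 3.62 ± 0.124 (adjusted p = 3.5e-12). Cdkn1a (ENSMUSG00000023067, chromosome 17, start 29090976, end 29100727), which codes for the cell cycle inhibitor p21, rose from 520 ± 45.1 to 3321 ± 675, a 6.30-fold change with adjusted p = 3.7e-05. Other large rises were Eda2r, a receptor of the TNF receptor family (log2 3.02 ± 0.215), the stress cytokine Gdf15 (2.58 ± 0.167), Dglucy (3.09 ± 0.127) and the matrix protein gene Tgfbi (1.32 ± 0.101, from 480 to 1186). The clock genes Npas2 and Arntl fell, from 557 to 244 (log2 -1.17 ± 0.182) and from 532 to 284 (-0.91 ± 0.143). Hc, which codes for complement C5, fell by 0.68 on the log2 scale (SE 0.103). Each of these genes except Tgfbi and Hc was among the largest rises or falls, where the 4 libraries of a group did not overlap those of the other.

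By group, 26 of 30 p53 targets rose and 0 fell (28 and 0 when adjusted over the list alone), with a median log2 change of 1.23. The camera test gave adjusted p = 5.5e-63 and adjusted p = 0.00587 with an estimated correlation. Members included Bax (1.71 ± 0.116), which promotes apoptosis, and Mdm2 (0.64 ± 0.0839), the ligase that degrades p53. Of 18 senescence and secreted factor genes 5 rose and 0 fell (9 and 1 adjusted over the list alone), among them Plau (1.88 ± 0.34) and its receptor Plaur (1.19 ± 0.21). Their median was 0.35 (adjusted p = 5.33e-07, and adjusted p = 0.0467 with an estimated correlation). Of 44 matrix and TGF-beta genes 5 rose (9 adjusted over the list alone), including Col3a1 (0.43 ± 0.0832) and Mmp2 (0.58 ± 0.103), with adjusted p = 1.4e-06 and adjusted p = 0.0508 with an estimated correlation. With the leukocyte marker level as a covariate 15 p53 targets (median 1.17), 1 senescence gene and 1 matrix gene rose. The matrix count was 3 without sham replicate 3 or 4 or irradiated replicate 2, and 8 without irradiated replicate 3, with library weights or with DESeq2.

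Markers of cells that the gate should remove or that belong to the other fraction had higher levels in irradiated epithelial libraries. Of 10 neutrophil genes 5 rose (8 adjusted over the list alone), including S100a8, an abundant neutrophil protein, from 2.67 to 40.2 (log2 3.53 ± 0.621). The sham mean lies within the range that a count of 0 allows, and the log2 change was 3.90 with a pseudocount of 0.5 and 2.04 with 8. The neutrophil median was 2.05 (adjusted p = 3.07e-08, and adjusted p = 0.0803 with an estimated correlation). Of 14 leukocyte genes 4 rose (11 adjusted over the list alone; median 1.42, adjusted p = 5.04e-10, and adjusted p = 0.131 with an estimated correlation). Of 18 endothelial genes 6 rose (15 adjusted over the list alone), with Cldn5 at 1.37 ± 0.268 (median 0.96, adjusted p = 6.36e-15, and adjusted p = 0.125 with an estimated correlation). Among 10 macrophage genes 2 rose, Ccl6 and Ear2 (7 adjusted over the list alone; median 1.32, adjusted p = 1.58e-06, and adjusted p = 0.228 with an estimated correlation). Of 7 lymphocyte genes 1 rose, Igkc (1 adjusted over the list alone; adjusted p = 0.00275, and adjusted p = 0.33 with an estimated correlation). Of 11 pericyte genes Rgs5 (2.52 ± 0.381) and Itga1 rose (3 adjusted over the list alone; adjusted p = 9.16e-05, and adjusted p = 0.123 with an estimated correlation). Of 12 mesothelial genes only Rspo1 rose (3 adjusted over the list alone; median 0.68, adjusted p = 1.96e-06, and adjusted p = 0.298 with an estimated correlation). Has1 rose among 16 adventitial fibroblast genes (9 adjusted over the list alone and 3 with the replicate block; adjusted p = 0.00293, and adjusted p = 0.0695 with an estimated correlation). The neutrophil count was 2 without sham replicate 3 or irradiated replicate 2 or 4, 3 without sham replicate 4 and 1 with a mean of at least 50. The leukocyte count was 8 without sham replicate 2, 1 without sham replicate 3 or irradiated replicate 4, 2 without sham replicate 4 or irradiated replicate 2, 2 with the 2 groups alone and 1 with a mean of at least 50. The endothelial count was 2 without sham replicate 4 or irradiated replicate 4, 3 without irradiated replicate 1 or 2 and 13 without irradiated replicate 3. Library weights, the replicate block and DESeq2 gave 8, 9 and 9 leukocyte genes and 12, 12 and 13 endothelial genes, and 5 macrophage genes rose with the block. The leukocyte covariate ended the calls of the neutrophil and endothelial lists, and those of the leukocyte list by construction, since it is the mean level of that list. The mean leukocyte marker level went from 4.66 ± 0.594 (SD, log2 scale, n = 4) to 5.93 ± 0.465 (exact permutation p = 0.0286, the smallest the test allows), while the pan-epithelial level differed by -0.0555 (exact permutation p = 0.2).

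Other groups moved in few members. Of 31 inflammatory genes Lif (1.40 ± 0.181) and Saa3 (2.07 ± 0.397) rose (10 higher and 1 lower adjusted over the list alone; adjusted p = 7.91e-05, and adjusted p = 0.298 with an estimated correlation). The call for Saa3 ended without sham replicate 1, 2 or 4 (adjusted p = 0.0504, 0.0541 and 0.0701, in a range over all alternatives up to 0.909). Of 38 Notch genes Dll1 and Notch4 rose and Dtx4 fell (5 and 1 adjusted over the list alone; adjusted p = 0.464), and all 3 calls ended without irradiated replicate 2 among other libraries (highest adjusted p 0.145, 0.147 and 0.0838). Hes1, a main Notch target, had a log2 change of 0.04 (adjusted p = 0.901). Of 37 Wnt genes 2 rose, Sfrp2 and Rspo1, and 2 fell, Wnt2b and Fzd7 (4 and 4 adjusted over the list alone; adjusted p = 0.856). Of 20 YAP and TAZ targets Fjx1 rose (9 and 1 adjusted over the list alone; adjusted p = 0.00103, and adjusted p = 0.146 with an estimated correlation). Of 20 fatty acid genes Lpin1 and Fads2 rose (9 adjusted over the list alone; adjusted p = 0.00133, and adjusted p = 0.228 with an estimated correlation). Of 20 antigen presentation genes Tap1 and Nlrc5 rose (2 adjusted over the list alone; adjusted p = 0.0208, and adjusted p = 0.523 with an estimated correlation). Of 31 interferon genes Trim30a rose (1 adjusted over the list alone; adjusted p = 0.387). With the replicate block 4 inflammatory genes and 4 YAP and TAZ targets rose.

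Of 19 alveolar type 2 genes Hc, Muc1 and Sfta2 fell and 0 rose (3 and 0 adjusted over the list alone; adjusted p = 0.185), and the surfactant gene Sftpc had a log2 change of -0.02 (adjusted p = 0.944), or 0.0131 without sham replicate 1 and 0.0199 without irradiated replicate 4. Cbr2 rose among 17 club genes (1 and 1 adjusted over the list alone), whose median was -0.37 (adjusted p = 0.00596, and adjusted p = 0.535 with an estimated correlation). Of 22 ciliated genes Tppp3 fell (1 adjusted over the list alone; adjusted p = 0.742). Of 17 transitional alveolar genes Plaur rose (3 and 4 adjusted over the list alone; adjusted p = 0.158). Lpl rose among 17 alveolar fibroblast genes (2 adjusted over the list alone; adjusted p = 0.748) and Foxf1 among 15 smooth muscle genes (1 adjusted over the list alone; adjusted p = 0.0584). Of 6 erythroid genes Hba-a1 rose (1 adjusted over the list alone; adjusted p = 0.464). Of 20 dissociation stress genes Fosb (-0.44) and Fos (-0.33) fell (4 adjusted over the list alone; adjusted p = 0.625).

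In 9 lists limma called 0 members. The 35 cell cycle genes had a median of -0.42 (adjusted p = 1.55e-06, and adjusted p = 0.298 with an estimated correlation), with 0 called adjusted over the list alone, 9 at an unadjusted p under 0.05 and 0 by edgeR or DESeq2. Of 25 cholesterol synthesis genes 6 reached an unadjusted p under 0.05, with 4 called adjusted over the list alone, 0 by edgeR and 2 by DESeq2 (adjusted p = 0.000179, and adjusted p = 0.507 with an estimated correlation). Of 19 oxidative stress genes 5 reached that level, with 0 called adjusted over the list alone, 0 by edgeR and 2 by DESeq2 (adjusted p = 0.253). Of 14 pan-epithelial genes 5 did, with 1 higher and 4 lower adjusted over the list alone, 0 by edgeR and 3 by DESeq2 (adjusted p = 0.0685). The unfolded protein response (22 genes, adjusted p = 0.321), alveolar type 1 (19, 0.956), basal (6, 0.0744), mitochondrially encoded (15, 0.854) and glial lists (3 genes, too few for camera) had 1, 2, 1, 1 and 2 members at an unadjusted p under 0.05. For these 5 lists 0 were called by edgeR or DESeq2, and adjusted over the list alone 1 glial gene was called and 0 in the other lists.

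Among the named epithelial genes the calls for Ccl6, Ear2, Igkc, Itga1, Rspo1, Has1, Sfrp2, Wnt2b, Fzd7, Fjx1, Fads2, Tap1, Nlrc5, Trim30a, Muc1, Sfta2, Lpl, Foxf1 and Hba-a1 ended when certain single libraries were left out (adjusted p up to 0.193). Sham replicate 3 and irradiated replicate 2 ended 33 of the named calls each, irradiated replicate 4 ended 28 and sham replicate 4 ended 27.

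In all, limma called 522 of 16626 genes in the irradiated epithelium, 376 higher and 146 lower, with 196 higher and 5 lower at least 2-fold. Groups did not overlap for 8.83% of genes, where chance gives 2.86% on average over groupings. Genes are correlated, so a single grouping can lie far from that average, here and in the comparisons below. The count was 275 without sham replicate 3, 287 without sham replicate 4, 214 without irradiated replicate 2 and 302 without irradiated replicate 4. With the leukocyte marker level as a covariate it was 39, which ended the calls for Npas2, Arntl, Hc, S100a8, Cldn5, Plau, Plaur and Col3a1 but not those for Phlda3, Cdkn1a, Eda2r, Gdf15, Dglucy and Tgfbi. Library weights gave 964 and DESeq2 816. Removal of the trend on gene length and GC content gave 364 higher and 319 lower, which changed the balance of directions.

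The same comparison in the mesenchyme showed the p53 targets Cdkn1a, from 618 ± 98.4 to 2659 ± 306 (SD, n = 4; log2 2.11 ± 0.121, adjusted p = 2.1e-07), and Eda2r, from 102 to 485 (2.24 ± 0.0929, adjusted p = 1.39e-09). Gdf15 rose by 1.94 and Ass1, an enzyme of arginine synthesis, from 26.2 to 98.7 (1.90 ± 0.198). C3, the central complement component, rose from 23419 to 36719 (0.65 ± 0.114). Lyve1, a marker of lymphatic endothelium that some macrophages also carry, rose from 34.0 to 180 (2.43 ± 0.367). Insig1, a regulator of cholesterol synthesis, fell by 0.61 on the log2 scale (SE 0.0997), and Fastkd2, a mitochondrial RNA-binding protein gene, fell by 0.70. Each of these except C3 and Insig1 was among the largest rises or falls, with no overlap between the libraries of the groups.

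Of 30 p53 targets 24 rose and 0 fell (25 and 0 adjusted over the list alone), with a median of 0.91 (adjusted p = 4.87e-36, and adjusted p = 0.004 with an estimated correlation). Of 31 inflammatory genes 11 rose and 0 fell (21 and 0 adjusted over the list alone), among them the chemokine Ccl7 (0.80 ± 0.134), the adhesion molecule Icam1 (0.75 ± 0.115) and C3. Their median was 0.43 (adjusted p = 1.66e-13, and adjusted p = 0.026 with an estimated correlation). The inflammatory count was 7 without sham replicate 1 or depleted replicate 1, and 5 without sham replicate 3 or 4 or irradiated replicate 2 or 4. It was 1 with the leukocyte covariate, 7 with no filter or with edgeR and 17 with DESeq2. The acute-phase gene Saa3 went from 45.9 ± 19.1 to 244 ± 174 (log2 2.21 ± 0.51, adjusted p = 0.0473), a call that ended without any of 10 single libraries (adjusted p up to 0.123). Of 18 senescence genes 7 rose and Igfbp3 fell (9 and 2 adjusted over the list alone), including Timp1 (0.86 ± 0.144) and Plau (0.87 ± 0.161), with adjusted p = 4.79e-06 and adjusted p = 0.026 with an estimated correlation. With the covariate 14 p53 targets (median 0.86) and 2 senescence genes rose, and the senescence count was 4 without sham replicate 3 or irradiated replicate 2. Of 25 cholesterol synthesis genes 5 fell and 0 rose, Idi1, Insig1, Msmo1, Sc5d and Hmgcs1 (10 adjusted over the list alone; median -0.29, adjusted p = 1.5e-06, and adjusted p = 0.215 with an estimated correlation). The cholesterol count was 9 without sham replicate 2, 1 without sham replicate 3 or irradiated replicate 2, and 2 without sham replicate 1 or 4, irradiated replicate 1 or 3, or depleted replicate 1 or 2. It was 3 with the 2 groups alone, and the covariate ended these calls. Of 40 Notch genes the ligand Dll1 (1.42 ± 0.243), Lfng and Numbl rose (5 adjusted over the list alone and 5 with the replicate block; adjusted p = 0.0263, and adjusted p = 0.215 with an estimated correlation).

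Leukocyte and epithelial markers were also higher in the irradiated mesenchymal fraction. Of 15 leukocyte genes Itgal and Vav1 rose (13 adjusted over the list alone; median 1.09, adjusted p = 1.1e-08, and adjusted p = 0.215 with an estimated correlation). Of 13 neutrophil genes 4 rose, Mmp9, Retnlg, S100a8 and S100a9 (9 adjusted over the list alone; median 1.29, adjusted p = 2.73e-07, and adjusted p = 0.119 with an estimated correlation). The S100a8 call ended without irradiated replicate 2 (adjusted p = 0.0558, in a range over all alternatives up to 0.546). Of 14 macrophage genes 4 rose, Csf1r, C1qc, Ctss and Siglecf (11 adjusted over the list alone; adjusted p = 1.3e-09, and adjusted p = 0.196 with an estimated correlation). The neutrophil count was at most 1 without any of irradiated replicates 1, 2 and 3 and sham replicates 1, 3 and 4, and the macrophage count at most 1 without any sham replicate but the second or without irradiated replicate 1 or 2. The replicate block gave 13 leukocyte and 9 macrophage genes, and the leukocyte covariate, made from the leukocyte list itself, ended the calls of these 3 lists. Of 12 lymphocyte genes Cd3e and Igkc rose (3 adjusted over the list alone; adjusted p = 8.55e-05, and adjusted p = 0.233 with an estimated correlation). Of 14 pan-epithelial genes Krt8 (0.89) and Cldn3 (1.07) rose (10 adjusted over the list alone; median 0.86, adjusted p = 1.05e-06, and adjusted p = 0.196 with an estimated correlation). With the replicate block 6 pan-epithelial and 4 lymphocyte genes rose. The mean leukocyte level went from 5.16 ± 0.551 to 6.24 ± 0.426 and the pan-epithelial level from 4.08 to 4.97 (SD, n = 4; exact permutation p = 0.0286 for each).

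Among the epithelial cell type lists Abca3 rose of 18 alveolar type 2 genes (10 adjusted over the list alone; adjusted p = 1.38e-08, and adjusted p = 0.215 with an estimated correlation). Krt7 rose of 19 alveolar type 1 genes (12 and 1 adjusted over the list alone; adjusted p = 1.08e-06, and adjusted p = 0.215 with an estimated correlation). Krt8 and Plaur rose of 14 transitional genes (4 adjusted over the list alone; adjusted p = 2.52e-05, and adjusted p = 0.057 with an estimated correlation). Cbr2 rose of 16 club genes (7 and 1 adjusted over the list alone; adjusted p = 2.04e-05, and adjusted p = 0.192 with an estimated correlation). Of 12 mesothelial genes Rspo1 rose (2 adjusted over the list alone; adjusted p = 0.00031, and adjusted p = 0.252 with an estimated correlation). Of 16 adventitial fibroblast genes Ccl11 rose (1 adjusted over the list alone; adjusted p = 0.892). With the replicate block 8 alveolar type 2, 10 alveolar type 1, 5 transitional and 3 mesothelial genes rose. The matrix gene Col1a1 had a log2 change of -0.06 (adjusted p = 0.915), or 0.0308 without sham replicate 4 and 0.104 without irradiated replicate 4. Of 14 mitochondrially encoded genes mt-Nd3 fell (7 adjusted over the list alone; adjusted p = 2.03e-05, and adjusted p = 0.236 with an estimated correlation), and 4 fell with the block.

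Of 34 interferon genes Zbp1 and Parp14 rose and Ifit2 fell (3 and 1 adjusted over the list alone; adjusted p = 0.000103, and adjusted p = 0.244 with an estimated correlation). Tap1 rose of 20 antigen presentation genes (5 adjusted over the list alone; adjusted p = 5.01e-05, and adjusted p = 0.235 with an estimated correlation), and 8 rose with the replicate block. Hmox1 and Mt2 rose of 18 oxidative stress genes (4 adjusted over the list alone; adjusted p = 0.0212, and adjusted p = 0.215 with an estimated correlation). Ccnd1 and Rspo1 rose of 35 Wnt genes (3 and 2 adjusted over the list alone; adjusted p = 0.612), Nuak2 and Ptpn14 of 20 YAP and TAZ targets (3 and 1 adjusted over the list alone; adjusted p = 0.388), and Hspa1b of 20 dissociation stress genes (4 adjusted over the list alone; adjusted p = 0.892).

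limma called 0 members of 11 lists. Of 18 endothelial genes 12 reached an unadjusted p under 0.05, with 12 higher adjusted over the list alone, 0 by edgeR and 9 by DESeq2 (median 0.91, adjusted p = 7.01e-09, and adjusted p = 0.215 with an estimated correlation). Of 17 alveolar fibroblast genes 10 did, with 9 lower adjusted over the list alone, 0 by edgeR and 3 by DESeq2 (median -0.33, adjusted p = 2.69e-05, and adjusted p = 0.215 with an estimated correlation). Of 10 ciliated genes 5 did, with 4 higher adjusted over the list alone, 1 by edgeR and 2 by DESeq2 (adjusted p = 0.00266, and adjusted p = 0.184 with an estimated correlation). Of 20 fatty acid genes 4 did, with 0 by edgeR and 1 by DESeq2 (adjusted p = 0.0707). The cell cycle (30 genes, adjusted p = 0.197), unfolded protein response (21, 0.784), smooth muscle (15, 0.111), pericyte (14, 0.892), erythroid (7, 0.0754), glial (7, 0.419) and basal lists (3 genes, too few for camera) had 6, 2, 4, 1, 1, 0 and 1 members at that level and 0 called by edgeR or DESeq2. Adjusted over the list alone 1 basal gene was called and 0 in the fatty acid list and the rest of these 7.

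Of the named mesenchymal genes, the calls for Idi1, Sc5d, Hmgcs1, Lfng, Numbl, Itgal, Vav1, Mmp9, Retnlg, S100a9, Csf1r, C1qc, Ctss, Siglecf, Cd3e, Krt8, Cldn3, Abca3, Krt7, Plaur, Rspo1, mt-Nd3, Parp14, Ifit2, Hmox1, Mt2 and Hspa1b ended when certain single libraries were left out (adjusted p up to 0.162). Sham replicate 3 ended 39 of the named calls, irradiated replicate 2 ended 37 and sham replicate 4 ended 30.

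In the mesenchyme limma called 631 of 16624 genes, 439 higher and 192 lower, with 217 higher and 7 lower at least 2-fold. Groups did not overlap for 11.8% of genes, where chance gives 2.86%. The count was 349, 1073, 193 and 366 without sham replicate 1, 2, 3 and 4, and 184 without irradiated replicate 2. It was 51 with the leukocyte covariate, which ended the calls for Lyve1, Icam1, Insig1, Timp1, Dll1 and Fastkd2 and that for C3 (adjusted p = 0.053), but not those for Cdkn1a, Eda2r, Gdf15, Ass1 and Ccl7. Replicate number as a block gave 1048 and DESeq2 1055. Removal of the length and GC trend gave 359 higher and 423 lower.

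Whether the compartments responded differently was tested on 15092 genes. Phlda3 rose more in the epithelium (3.62) than in the mesenchyme (0.78), with a difference of 2.84 ± 0.152 on the log2 scale (adjusted p = 9.23e-12). The p53 target Ccng1 changed by 2.17 and 0.83 (adjusted p = 0.000288), and Tgfbi by 1.32 and -0.22 (adjusted p = 0.00269). Keratin 8 (Krt8) changed by -0.25 in the epithelium and 0.89 in the mesenchyme (adjusted p = 0.0133). In the irradiated mesenchyme the mean pan-epithelial level was higher by 0.889 (exact permutation p = 0.0286), close to the change of Krt8. Of its members Krt8 itself and Cldn3 were called over all genes, and more when adjusted over the list alone, as given above. The Krt8 difference therefore cannot be told apart from a larger amount of epithelial cells in that fraction. The pentraxin Ptx3 changed by -0.43 and 1.48 (adjusted p = 0.0206). No difference passed for Cdkn1a (0.55, adjusted p = 0.291) or Eda2r (0.79, adjusted p = 0.117). limma called 95 genes, 30 with a log2 change that was higher in the epithelium than in the mesenchyme and 65 with one that was lower. The count was 199 with library weights, 184 with replicate number as a block, 153 with edgeR and 441 with DESeq2. Residuals of the same treatment and number correlated across the compartments (median 0.107), which the test without a block leaves out. The count was 50, 58, 48 and 50 without epithelial sham replicate 3 or 4 or irradiated replicate 2 or 4, 334 and 51 without mesenchymal sham replicate 2 or 3, and 50 and 173 without mesenchymal irradiated replicate 2 or 3. Of the genes higher after irradiation, 371 in the epithelium and 413 in the mesenchyme, 142 were shared where 10.2 would be with independence (one-sided Fisher exact p = 2.52e-130). Of 130 and 189 lower genes 2 were shared (1.63 with independence, one-sided Fisher exact p = 0.486). Genes are not independent replicates in these tests, and independence assumes that the compartments do not share mice, which is not stated. The mean leukocyte marker level also rose in both fractions after irradiation, by 1.27 and 1.07 on the log2 scale. The overlap of higher genes therefore does not tell a shared response from shared admixture.

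The second question was what neutrophil depletion changed in irradiated mice. In the epithelium Saa3 (ENSMUSG00000040026, chromosome 7, start 46711998, end 46715700), an acute-phase serum amyloid, rose from 34.1 ± 25.1 in irradiated to 509 ± 168 in depleted mice (SD, n = 4; 16.2-fold, adjusted p = 0.00114), against 6.53 ± 2.8 in sham. Retnla, a resistin-like protein gene of type 2 responses, rose from 86.9 to 439 ± 179 (log2 2.24 ± 0.289, sham 90.5). The metallothionein gene Mt2 rose from 96.6 to 334 (1.75 ± 0.237) and the collagen gene Col3a1 from 2567 to 3936 (0.61 ± 0.0832). The ribosomal protein genes Rpl26 (-0.68 ± 0.109) and Rpl35a (-0.64 ± 0.0925) fell. Csf3r, the receptor of the neutrophil growth factor G-CSF, had means of 63.8 and 12.8 in irradiated and depleted mice and did not pass (log2 -2.11, adjusted p = 0.0855).

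Of 30 p53 targets limma called 0, with 0 adjusted over the list alone, 6 at an unadjusted p under 0.05, 0 by edgeR and 1 by DESeq2 (median 0.17, adjusted p = 0.00177, and adjusted p = 0.823 with an estimated correlation). Cdkn1a changed by 0.25 (adjusted p = 0.661). Saa3 alone rose of 31 inflammatory genes (3 adjusted over the list alone; adjusted p = 0.000774, and adjusted p = 0.823 with an estimated correlation). Of 44 matrix genes Col3a1 and Timp1 rose (2 and 1 adjusted over the list alone), but the Timp1 call ended without any of 9 single libraries (adjusted p up to 0.12). Of 38 Notch genes limma called 0, with 0 adjusted over the list alone, 6 at an unadjusted p under 0.05 and 0 by edgeR or DESeq2 (adjusted p = 0.53). Of 10 neutrophil genes limma called 0, with 1 lower adjusted over the list alone, 2 at an unadjusted p under 0.05, 0 by edgeR and 1 by DESeq2 (median -0.16, adjusted p = 0.723). S100a8 changed by 0.91 (adjusted p = 0.614). Of 12 mesothelial genes limma called 0, with 5 higher adjusted over the list alone, 6 at an unadjusted p under 0.05, 0 by edgeR and 2 by DESeq2 (median 0.63, adjusted p = 6.71e-07, and adjusted p = 0.823 with an estimated correlation).

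limma called 79 genes between depleted and irradiated epithelium, 34 higher and 45 lower, with 13 higher and 23 lower at least 2-fold. Groups did not overlap for 6.41% of genes, where chance gives 2.86%. The count was 43, 36 and 49 without irradiated replicate 1, 3 and 4, and 43 and 199 without depleted replicate 1 and 3. A mean of at least 50 gave 52, a fit of the 2 groups alone 32 and DESeq2 289. Equal totals gave 53 higher and 44 lower, which turned the balance of directions.

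In the mesenchyme, with the pseudocount of 1, the largest rise after depletion among the named genes was that of Cxcl5, a rank that a larger pseudocount may change. Cxcl5 (ENSMUSG00000029371, chromosome 5, start 90759360, end 90761624), a chemokine for neutrophils, rose from 1.98 ± 1.17 in irradiated to 100 ± 49.6 in depleted mice (SD, n = 4; 32.4-fold after a pseudocount of 1, adjusted p = 4.73e-05), against 0.713 ± 0.483 in sham. The irradiated mean lies below the limit that a count of 0 allows, so the size depends on the pseudocount (log2 5.02, against 5.31 with 0.5 and 3.31 with 8). Saa3 rose from 244 ± 174 to 5783 ± 2493 (26.6-fold, adjusted p = 0.00146). Lcn2 (ENSMUSG00000026822, chromosome 2, start 32384633, end 32388252), an iron-binding acute-phase protein, rose from 91.9 ± 63.0 to 1439 ± 837 (16.4-fold, adjusted p = 0.00371). Csf3, which codes for G-CSF, rose from 6.99 to 92.9 (log2 3.54 ± 0.482). Csf3r (ENSMUSG00000028859, chromosome 4, start 126024550, end 126044440), its receptor, fell from 145 ± 76.2 to 24.7 ± 5.24 (log2 -2.37 ± 0.391, adjusted p = 0.00711). The adhesion molecule gene Chl1 rose from 30.4 to 455 (3.91 ± 0.308), Ptx3 from 151 to 1052 (2.77 ± 0.36), and Nav2 fell from 3229 to 2004 (-0.70 ± 0.104).

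**Figure D1:**
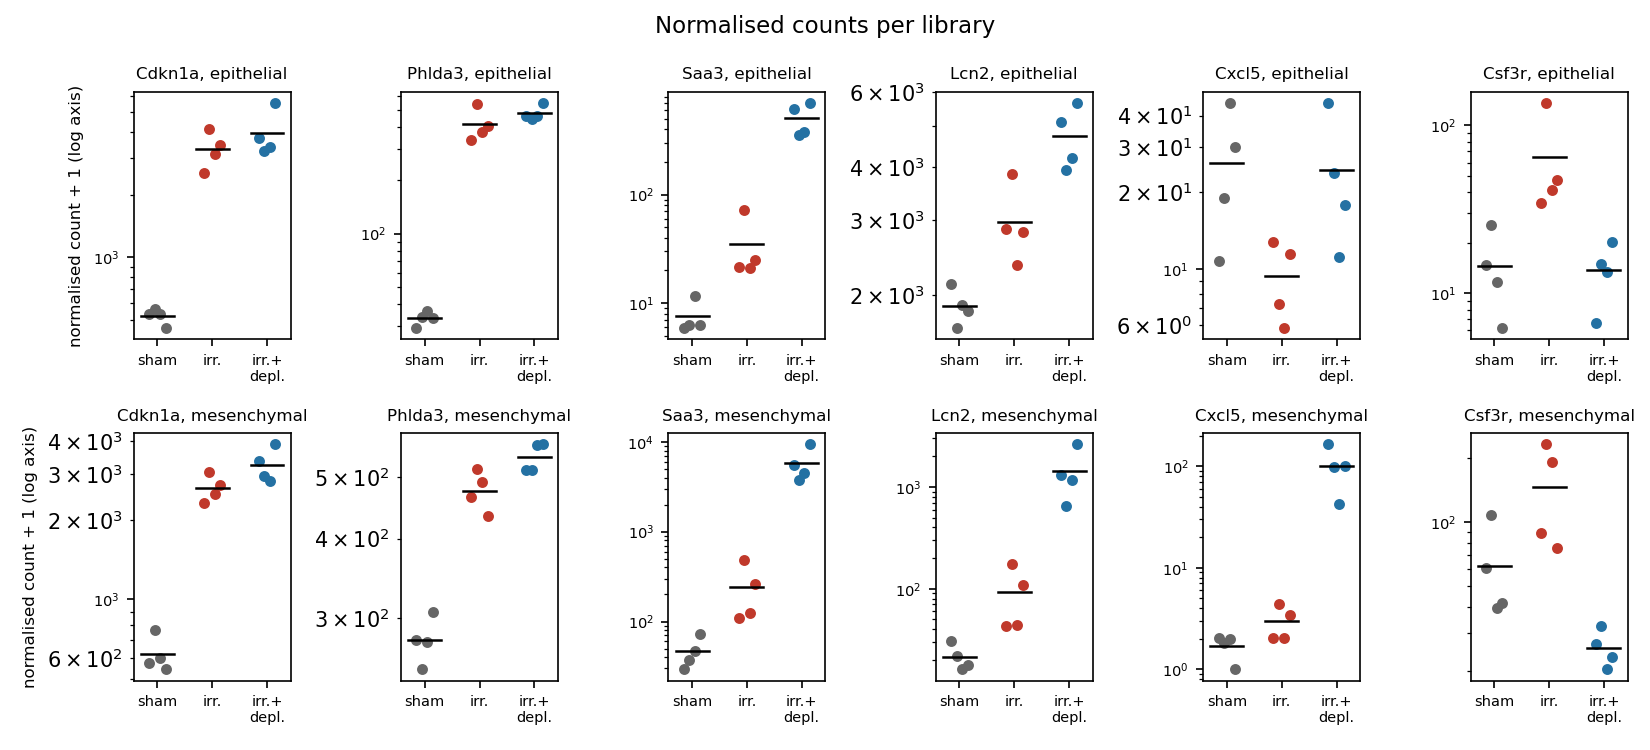
Normalised count + 1 on a log axis for 6 genes (Cdkn1a, Phlda3, Saa3, Lcn2, Cxcl5 and Csf3r) in sham, irradiated and depleted mice of each compartment; points are libraries and lines are group means. Cxcl5 in the mesenchyme averaged 0.713, 1.98 and 100, and Csf3r 61.4, 145 and 24.7.

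Of 31 inflammatory genes 16 rose and 0 fell (18 and 2 adjusted over the list alone), among them Il33 (2.08 ± 0.179), an alarmin cytokine, Ccl7 (1.43 ± 0.134) and Ptgs2 (1.35 ± 0.119), the inducible cyclooxygenase. Their median was 0.57 (adjusted p = 6.69e-14, and adjusted p = 0.0583 with an estimated correlation). Of 21 unfolded protein response genes 8 rose and 0 fell (15 and 1 adjusted over the list alone), with Manf at 0.70 ± 0.125 and the transcription factor Xbp1 at 0.48 ± 0.0986. Their median was 0.42 (adjusted p = 1.2e-10, and adjusted p = 0.218 with an estimated correlation). The unfolded protein response count was 3 without depleted replicate 1, 5 without irradiated replicate 1 or 3 or depleted replicate 4, 5 with the leukocyte covariate and 13 with DESeq2. Of 18 senescence genes 5 rose, Timp1 (1.61 ± 0.144), Igfbp4, Cxcl1, Il6 and Mmp3 (7 and 2 adjusted over the list alone; adjusted p = 0.00408, and adjusted p = 0.203 with an estimated correlation). Of 18 oxidative stress genes 4 rose, Mt2 (2.02 ± 0.215), Mt1, Sod2 (1.10 ± 0.131) and Txn1 (6 adjusted over the list alone; adjusted p = 0.000401, and adjusted p = 0.203 with an estimated correlation), a count that was 2 without depleted replicate 1. Of 44 matrix genes 4 rose, Timp1, Lox, Col4a1 and Col4a2, and Timp3 fell (4 and 2 adjusted over the list alone; adjusted p = 0.932). The matrix rises numbered 1 without irradiated replicate 3 or 4 or depleted replicate 1, and 2 without irradiated replicate 1 or depleted replicate 4, with no filter, with the 2 groups alone or with the covariate.

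Of 20 fatty acid genes Pnpla3, Gpam and Elovl6 rose (4 adjusted over the list alone; adjusted p = 0.0297, and adjusted p = 0.49 with an estimated correlation). Of 25 cholesterol synthesis genes limma called 2 higher and 0 lower (7 and 0 adjusted over the list alone; median 0.29, adjusted p = 9.5e-06, and adjusted p = 0.49 with an estimated correlation). Of the 5 that fell after irradiation, Idi1 (0.50, adjusted p = 0.107), Hmgcs1 (0.34, adjusted p = 0.0744), Msmo1 (0.29) and Insig1 (0.16) had higher levels and Sc5d a lower level (-0.17), and none of these changes passed. Both comparisons use the irradiated libraries, so noise in these moves the 2 changes in opposite directions. By limma the cholesterol count was 0 without any 1 irradiated replicate, without depleted replicate 1 or 4 or with the leukocyte covariate, and 1 with the 2 groups alone. It was 4 without sham replicate 2 or with library weights, and 5 without depleted replicate 3 or with DESeq2. Reg3g and Hp rose of 16 club genes (3 adjusted over the list alone; adjusted p = 0.00357, and adjusted p = 0.49 with an estimated correlation). Fas (0.46) rose of 30 p53 targets and Dtx4 (0.44) of 40 Notch genes, while Cdkn1a changed by 0.29 (adjusted p = 0.221). Of 13 neutrophil genes Csf3r and Cxcr2 fell (2 adjusted over the list alone; median -0.46, adjusted p = 0.342), and S100a8 changed by 0.66 (adjusted p = 0.451). The Cxcr2 call ended without any of 9 single libraries (adjusted p up to 0.132). Of 15 leukocyte genes limma called 0, with 1 at an unadjusted p under 0.05 and 0 by edgeR or DESeq2 (median -0.41, adjusted p = 0.0191, and adjusted p = 0.847 with an estimated correlation). The mean leukocyte level differed by -0.387 (exact permutation p = 0.257) and the pan-epithelial level by 0.113 (exact permutation p = 0.571).

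The calls for Fas, Mt1, Txn1, Lox, Col4a1, Timp3, Pnpla3, Gpam, Elovl6 and Hp ended when certain single libraries were left out (adjusted p up to 0.106). Depleted replicate 1 ended 26 of the named calls, irradiated replicate 3 ended 21 and depleted replicate 4 ended 19.

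limma called 448 genes between depleted and irradiated mesenchyme, 336 higher and 112 lower, with 80 higher and 26 lower at least 2-fold. Groups did not overlap for 10.02% of genes, where chance gives 2.86%. The count was 218 and 262 without irradiated replicate 3 and 4, and 182, 806 and 198 without depleted replicate 1, 3 and 4. A fit of the 2 groups alone gave 291, the leukocyte covariate 274 and DESeq2 785. Of the genes higher in depleted mice, 32 in the epithelium and 315 in the mesenchyme, 13 were shared where 0.668 would be with independence (one-sided Fisher exact p = 2.71e-14), and 3 lower genes were shared (0.277 with independence, exact p = 0.00265). The correlation between libraries of the same number across the compartments (median 0.107) is ignored by these independent values. Whether depletion acted differently in the compartments was not tested.

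Depleted mice were also compared with sham. Cdkn1a was higher by 2.90 (log2) in the epithelium and 2.40 in the mesenchyme, and Phlda3 by 3.84 in the epithelium. Saa3 was higher by 6.08 and 6.94, Lcn2 in the mesenchyme by 5.93 and Il33 by 2.17. Of 30 p53 targets 27 rose in the epithelium (29 adjusted over the list alone; median 1.48, adjusted p = 0.0202 with an estimated correlation) and 25 in the mesenchyme (26 adjusted over the list alone; median 1.08, adjusted p = 0.00657 with an estimated correlation). Of 31 inflammatory genes 23 rose in the mesenchyme (23 adjusted over the list alone; median 0.76, adjusted p = 0.00657 with an estimated correlation) and 9 rose and 1 fell in the epithelium (13 and 2 adjusted over the list alone; adjusted p = 0.301 with an estimated correlation). Of 35 cell cycle genes 7 fell in the epithelium (9 adjusted over the list alone; median -0.46, adjusted p = 5.88e-06, and adjusted p = 0.327 with an estimated correlation). The cell cycle count was 4 without sham replicate 1 or 4, 3 without sham replicate 3 or depleted replicate 4 and 3 with a mean of at least 50. The leukocyte covariate ended the cell cycle calls and left 3 inflammatory genes higher in the epithelium. limma called 1876 genes in the epithelium, 1084 higher and 792 lower, and 2528 in the mesenchyme, 1415 higher and 1113 lower. The epithelial count was 1187 without sham replicate 3 and the mesenchymal count 1571 without sham replicate 3 and 1660 without depleted replicate 1. With the leukocyte covariate the counts were 186 and 1395. Of the 522 genes called in the irradiated epithelium 429 were also called here in the same direction, and of 631 in the mesenchyme 469. The comparisons share the sham libraries, and with different sham libraries in each comparison the overlap averaged 140 and 144 genes. Those smaller fits also called fewer genes, a mean of 253 and 916 in the epithelium and 398 and 1419 in the mesenchyme. In 20 simulations without a change 0 genes were shared by limma calls. All groups had equal gene means there, so few calls could arise, and the 0 does not show what shared sham libraries add. The log2 changes of the 2 comparisons still correlated at 0.498 and 0.499 in these simulations, against 0.706 and 0.721 in the data (epithelium and mesenchyme).

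The last question was whether depletion moved the irradiation response back towards sham. The score, in log2 units with sham at 0, was 0.629 ± 0.151 in irradiated and 0.805 ± 0.082 in depleted epithelium (SD, n = 4; 1431 genes). The difference of 0.175 did not pass (exact permutation p = 0.114). In the mesenchyme the score was 0.595 ± 0.0987 and 0.818 ± 0.0924 (2195 genes), a difference of 0.223 (exact permutation p = 0.0571). Depleted mice had the higher mean score in both compartments, and no return towards sham was measured. The epithelial difference passed without irradiated replicate 2 (0.252), and the mesenchymal difference without sham replicate 3 (0.331), sham replicate 4 (0.259) or irradiated replicate 2 (0.310), each with exact permutation p = 0.0286. Irradiated replicate 2 (0.822 and 0.738) was the only irradiated library above the lowest depleted score (0.724 and 0.688). Without it the test has fewer assignments and gives the smallest p that these allow, so that p adds little.

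**Figure D2:**
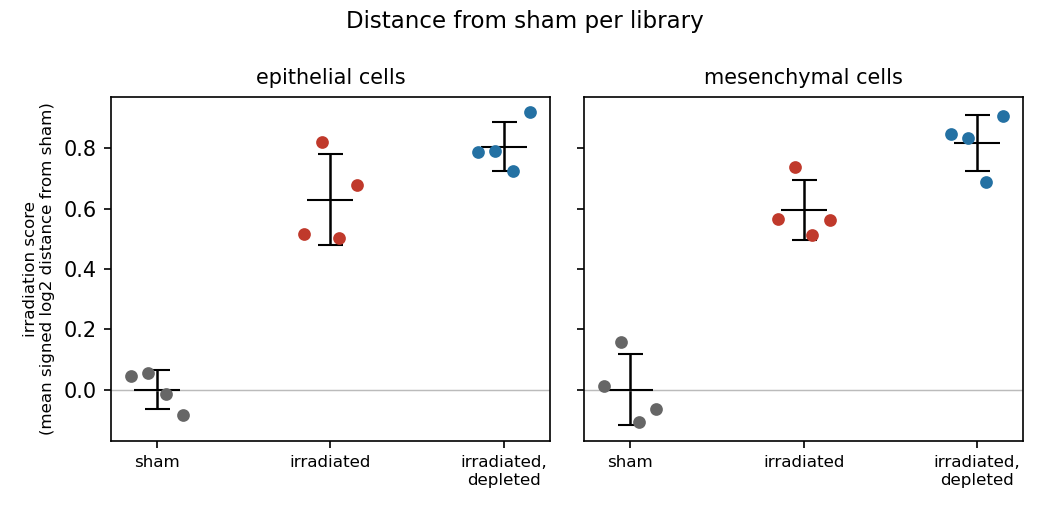
Irradiation score per library, the mean log2 distance from sham signed by the direction of each gene, in sham, irradiated and depleted mice with 1 panel per compartment; points are libraries and bars are the mean ± SD of 4. Mean scores were 0.629 and 0.805 in irradiated and depleted epithelium and 0.595 and 0.818 in mesenchyme.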

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

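The tests for admixed leukocytes, admixed epithelial cells, depth (thinned reads) and genes shared by the compartments given here were chosen after the data were seen, and the other tests of this part were not.

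Among 546 groups of 4 libraries, 28 held a library whose gap to the nearest other, as a share of the range of the group, passed the 95% limit of Dixon's test, where chance gives about 1 in 20 groups, or 27.3. For levels of gene lists the gap was 0.848 of the range for interferon genes in epithelial sham replicate 2 and 0.853 for ciliated genes in sham replicate 1. In irradiated epithelium it was 0.931 for Notch genes (replicate 2), 0.899 for YAP and TAZ targets (replicate 3), 0.837 for erythroid genes (replicate 3) and 0.846 for pan-epithelial genes (replicate 4). In the mesenchyme it was 0.841 for Wnt genes (irradiated replicate 1) and 0.92 for smooth muscle genes (depleted replicate 3). For single genes in epithelial sham libraries the share was 0.853 for Mki67 and 0.906 for Rlbp1 (replicate 2), 0.868 for Mst1r (replicate 4) and 0.927 for Saa3 (replicate 3). In irradiated epithelium it was 0.926 for Hes1 (replicate 4), 0.885 for Mki67, at 286.8 in replicate 1 against 73.95 to 98.49, and 0.924 for Saa3, at 71.7 in replicate 2 against 20.23 to 24.12. In depleted epithelium it was 0.862 for Psrc1 and 0.877 for Tg (both replicate 4). In mesenchymal sham libraries it was 0.914 for Hey1 (replicate 1) and 0.889 for Ryr3 (replicate 2). In irradiated mesenchyme it was 0.865 for Acta2, at 6588 in replicate 1 against 3386 to 3817, and 0.849 for Sox9, at 165 in replicate 1 against 41.7 to 60.32. There it was also 0.848 for Ggnbp1 (replicate 1), 0.86 for Nav2 and 0.939 for Nckap5 (replicate 4), and 0.831 for Ptprc (replicate 2). In depleted mesenchyme it was 0.866 for Lyve1 (replicate 3), 0.875 for Ptprc (replicate 2) and 0.915 for Saa1, at 253 in replicate 4 against 46.12 to 63.78.

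The irradiation response differed between the compartments for 95 genes by the test of the difference. The log2 change in the epithelium minus that in the mesenchyme was, among others, 2.84 for Phlda3, 1.84 for Dglucy, 1.54 for Tgfbi and 1.35 for Ccng1. It was -1.01 for Ass1, -1.15 for Kcnk3, -1.14 for Krt8 and -1.90 for Ptx3. Kcnk3 changed by -0.93 in the epithelium and 0.22 in the mesenchyme, so its epithelial change was the larger in size.

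The rise of 16 of 31 inflammatory genes in depleted against irradiated mesenchyme is a pattern for which sources in other cells were weighed. The leukocyte level differed by -0.387 between depleted and irradiated libraries (exact permutation p = 0.257). With it as a covariate 13 of the 16 genes were still called. These values argue against a larger amount of admixed leukocytes as the whole cause. They do not cover a change of expression or of cell type within admixed leukocytes. The 32 pan-epithelial and alveolar type 2 markers had a median change of -0.0469 (SD 0.319) against 1.15 for the called genes. This argues against a larger amount of these epithelial cells as the whole cause. It does not cover a change of expression within admixed epithelial cells. Nor does it cover club cells, of whose markers Reg3g and Hp rose as given above. With reads thinned to 1 depth 16 of the called genes were still called, which excludes depth. A shift among the cell types of the mesenchymal fraction was not tested. With the replicate block, camera at the preset correlation gave lower pericyte and smooth muscle lists (adjusted p = 0.000355 and 0.00851). Alveolar and adventitial fibroblast lists did not pass there (adjusted p = 0.114 and 0.786). A response of mesenchymal cells to the loss of neutrophils or to the antibody stays open as a hypothesis that may account for the rise. No group had the antibody without irradiation. The loss of neutrophils itself was not shown by these libraries, which were sorted without CD45. Their neutrophil marker level differed by -0.262 (exact permutation p = 0.429), although Csf3r and Cxcr2 fell as given above.

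For each count of changed genes within a table, 1 of the 35 splits of the 8 libraries, the real one, gave as many. This is the smallest share that 35 splits allow, and the counts were not adjusted for one another. Each other split puts libraries of both real groups together, which adds any real difference to the spread within a group. The splits therefore do not show what equal groups would give, and chance is not excluded by them. In the epithelium the real count and the highest of the other splits were 522 and 83 for irradiated against sham, 79 and 40 for depleted against irradiated, and 1876 and 1 for depleted against sham. In the mesenchyme they were 631 and 3, 448 and 31, and 2528 and 1. For the difference between the responses 1 of 100 splits, the real one, gave as many (95, highest other 58). With libraries of the same treatment and number kept together across the compartments, limma called 144 genes the same way in both for irradiated against sham and 16 for depleted against irradiated, and 0 in the other 34 splits of each. In most of those splits limma called no gene in either compartment, so they tell little about the overlap of as many calls.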

How the results depend on the processing

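Chosen after the data were seen were the leukocyte level as a covariate, the thinned reads and the removal of the length and GC trend; the other alternatives were planned. For the values given, the cause was not tested unless stated. Counts of changed genes for irradiated against sham were 964 with library weights, 816 with DESeq2 and 39 with the covariate in the epithelium (522 in the main test). In the mesenchyme they were 1048 with the replicate block, 1055 with DESeq2 and 51 with the covariate (631). The block gave 535 in the epithelium. The covariate is correlated with irradiation, which raised the median standard error 1.67 and 1.46 times, and the median size of the called changes fell from 0.71 to 0.43 and from 0.73 to 0.52 (log2). Of these genes 519 of 522 and 631 of 631 kept their sign. For depleted against irradiated the epithelial count was 52 with a mean of at least 50, 32 with the 2 groups alone, 289 with DESeq2 and 94 with the block (79). The mesenchymal count was 291 with the 2 groups alone, 274 with the covariate, 785 with DESeq2 and 548 with the block (448). For depleted against sham the covariate gave 186 (1876) and 1395 (2528), and the block 1780 and 2697. The difference between the responses counted 199 genes with weights, 184 with the block, 153 with edgeR and 441 with DESeq2 (95). Of 62 list tests called by camera in irradiated against sham and depleted against irradiated, 5 were called with an estimated correlation, which admits larger correlation between genes, and 66 with the block, where 4 calls differed. With reads thinned the counts stayed within 1.5 times of the main counts.

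With each library left out, which also leaves fewer samples, the epithelial counts ranged from 214 to 653 for irradiated against sham, from 36 to 199 for depleted against irradiated and from 1187 to 1934 for depleted against sham. The mesenchymal counts ranged from 184 to 1073, from 182 to 806 and from 1571 to 2732, and the difference between the responses from 48 to 334. The score difference ranged from 0.109 to 0.252 in the epithelium (exact p 0.0286 to 0.286) and from 0.164 to 0.331 in the mesenchyme (exact p 0.0286 to 0.0857), and stayed positive. With replicate number as a block, by exact sign flips, the score difference gave p = 0.25 in the epithelium (3 of 4 higher) and p = 0.125 in the mesenchyme (4 of 4 higher), the latter the smallest that 4 pairs allow. With genes chosen in other irradiated libraries than those scored it averaged 0.184 and 0.303. Over the 6 splits it ran from 0.0193 to 0.292 in the epithelium (73 to 839 genes chosen) and from 0.184 to 0.418 in the mesenchyme (69 to 404 genes). With a median over genes the score difference was 0.156 and 0.198.

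Directions turned in alternatives in which the gene was not called. The epithelial response to irradiation of Sftpc ranged from -0.0512 to 0.0199 with each library left out, and was 0.0131 without sham replicate 1. With the covariate it was -0.14 for Ear2 (called in the main test, 1.39), 0.148 for Scgb1a1 and -0.111 for Ptprc, and without the length and GC trend -0.00895 for Hes1. In the mesenchyme Acta2 ranged from -0.0913 to 0.344 with each library left out (-0.0341 and -0.0495 without sham replicate 3 and 4) and was -0.268 with the covariate. Col1a1 ranged from -0.272 to 0.104 (0.0308 without sham replicate 4) and was 0.000862 with DESeq2, and Ptprc was -0.327 with the covariate. Of the values of named genes under the alternatives, 1780 of 2112 and 1467 of 1878 kept direction and call for irradiated against sham in epithelium and mesenchyme, and 599 of 724 and 1471 of 1668 for depleted against irradiated. Depth limits genes near a normalised count of 10, since genes with fewer than 4 libraries at that level were not tested.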

Other observations

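The tests for depth, leukocytes and the hour of harvest were chosen after the data were seen, as were the satellite and clock gene sets, while the test for genomic DNA was set before its value was seen and the list tests were planned.

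Between depleted and irradiated mice further lists passed camera at its preset correlation alone, with 0 members called by limma. In the epithelium the 20 antigen presentation genes had a median log2 change of -0.26 (adjusted p = 5.46e-06, and adjusted p = 0.823 with an estimated correlation), with 0 called by limma, edgeR or DESeq2 and 9 at an unadjusted p under 0.05. The 22 unfolded protein response genes had a median of 0.08 there (adjusted p = 0.000971, and adjusted p = 0.823 with an estimated correlation), with 0 called by limma, 5 higher and 1 lower adjusted over the list alone, 8 at an unadjusted p under 0.05, 0 by edgeR and 1 by DESeq2. In the mesenchyme the 12 lymphocyte genes had a median of -0.77 (adjusted p = 0.00721, and adjusted p = 0.78 with an estimated correlation), with 0 called by limma, edgeR or DESeq2 and 4 at an unadjusted p under 0.05. The 18 endothelial genes had a median of -0.38 (adjusted p = 0.00408, and adjusted p = 0.847 with an estimated correlation), with 0 called by limma, edgeR or DESeq2 and 2 at an unadjusted p under 0.05. In the mesenchyme of depleted mice Slc39a14, a zinc and iron transporter gene, averaged 2847 against 585 in irradiated mice (log2 2.23 ± 0.209, adjusted p = 0.000312).

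In 13 genes the longest annotated transcript consists mostly of the mouse major satellite repeat. Matching 15-mers covered 75.8% to 93.2% of its bases, against at most 4.13% in other genes. Reads of these genes were higher in irradiated libraries. Of 9 tested in the epithelium 8 rose (median 3.27) and of 10 in the mesenchyme 10 rose (median 4.84, and 4.84 with Gm10721, at 0 in sham, at its bound of at least 19.5-fold higher), while limma called 0 between depleted and irradiated mice. Depth is excluded, since satellite reads relative to all reads rose 22.3 times or more. The deepest library held only 1.64 times the reads of the shallowest. This test took the place of one with thinned reads that had left the question undecided (medians 2.90 and 4.72, with 9 and 8 genes called). With the leukocyte level as a covariate the medians were 3.99 and 4.8 (5 of 9 and 6 of 10 genes called). These medians argue against a larger amount of admixed leukocytes as the whole cause. The covariate is correlated with irradiation, so they are not excluded by it. A change of expression within admixed leukocytes is not covered. Genomic DNA carried over cannot be told apart from RNA, as reads in 1625 receptor genes of the smell organs, which lung cells should not express, changed 0.957 times in the epithelium (95% bootstrap interval 0.849 to 1.07, exact permutation p = 0.590) and 1.41 times in the mesenchyme (1.19 to 1.69, exact permutation p = 0.00606). Transcription of the repeat after irradiation may be a source and stays open as a hypothesis, and how reads were placed among the copies is not known.

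Clock genes of opposite phase moved apart in irradiated libraries. Of 4 genes in the phase of Arntl 2 fell in the epithelium (median -0.61) and 3 in the mesenchyme (-0.51), and of 11 in the phase of Per genes 7 rose (1.06) and 6 rose (0.86), with Per2 at 1.12 and 1.25. The gap between the phase medians was 1.66 in the epithelium and 1.37 in the mesenchyme. With the leukocyte level as a covariate it was 1.21 and 1.05, though the epithelial calls for Arntl and Npas2 ended. The covariate is correlated with irradiation and the gaps have no error, so admixed leukocytes are not excluded. The phases moved apart in both compartments and in both irradiated groups against sham (smallest gap 0.857), although Nfil3 of the Arntl phase was higher in depleted mice. A harvest at another hour of the day may account for this shift. The test for it was set after the shift was seen and restates it, so it decides nothing. The hour of harvest is not given, so an effect of irradiation on the clock stays open as well.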
